A study of Mus musculus with 48 samples.

How the data were processed

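The series holds 48 RNA-seq libraries of mouse liver, from 12 zeitgeber times in wild-type and Nono-/- mice and from total and nuclear RNA of the same liver samples, each a pool of 2 mice. Per the labels' protocols, mice of 14 weeks were fed only in the dark phase, and libraries were made with the TruSeq Stranded Total RNA kit with Ribo-Zero Gold, which removes ribosomal RNA. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.0k and the genome build mm10. Per the file headers, the values are FPKM that the authors computed with HOMER's analyzeRepeats.pl over the exons or the introns of each gene, with gene isoforms condensed to 1 entry. No strand option is written in the headers and the version of HOMER is not given in the sources used here, so reads of genes that overlap on opposite strands were treated as inseparable. Of the 98 genes named by the rule below, 26 overlap another gene of the tables, 11 of them on the other strand. The exon values cover 24453 genes and the intron values 20771, and all 96 columns of per-library values were used.

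Whole reads leave steps in FPKM values, so the depth behind each library was worked out from the low values and the gene lengths in the tables. Between 99.79% and 100% of the values read as 1 to 10 reads came out whole within 0.1 read. This gave depths of 9.91 to 28.94 M reads, 11.8 to 23.9 M in wild-type total RNA, 9.91 to 22.5 M in Nono-/- total RNA, 14.7 to 21.7 M in wild-type nuclear RNA and 12.7 to 28.9 M in Nono-/- nuclear RNA. Depths were used to describe libraries and to set a limit of 3 reads over a group for genes listed at 0, which covers counting error only. The tests stayed on FPKM. No 2 of the 1128 pairs of libraries held identical values.

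Groups and times came from the sample labels. The libraries have no replicates at a time point, so the spread was taken from the residuals around a smooth daily curve, and p-values measure the spread between pools taken at different times. The numbers in the column names run in blocks by group, so the order of library handling cannot be told apart from group. Analyses used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9. Each library was divided by its median ratio to the geometric mean library, and values were taken as log2(FPKM + pseudocount), with a pseudocount of 0.1 for exons and 0.05 for introns. Genes with a mean of at least 0.5 FPKM (exons) or 0.1 FPKM (introns) were tested. Changes are on this log2 scale and relative to the median gene, and they understate changes of low genes. A limma model with trend held genotype, the cosine and sine of a 24 h period and their products with genotype. The genotype term gave the difference over the day, F tests of cosine and sine gave rhythms in each genotype, and the F test of the products gave the difference in rhythm. Dark libraries (ZT14 to ZT0) were compared with light libraries (ZT2 to ZT12) in a separate model. The nuclear to total ratio was tested on the difference of log2 values of the same liver, and the exon to intron ratio on the difference within a library. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05.

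There were 38 gene lists with 569 genes, of which 555 are in the exon table, for pathways of liver metabolism, the clock, nuclear RNA biology, stress, immunity and cell types. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists of a comparison. No list passed in any of the 6 comparisons with an estimated correlation. With fry 6, 15, 11 and 5 lists passed for the genotype effect in total exons, nuclear exons, total introns and nuclear introns, and 0 in both dark-light comparisons. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from the alternatives said to be chosen later. The rule named Nono first, then the 10 genes with the largest change each way in total RNA exons and nuclear introns (5 each way elsewhere) among those past the threshold, with at least 1 FPKM (exons) or 0.2 FPKM (introns) in the higher genotype and the same sign at 10 or more time points. It also named the 10 genes with the smallest p for a difference in rhythm with a peak-to-trough fold of at least 1.5, 5 each way for ratios, and 2 to 4 members of each list described. All core clock genes could be named. En2 exons, Taf1, Pspc1 and Sfpq in total RNA exons, and Ptbp1, Egr1 and G6pc in nuclear RNA exons were added after their values were seen.

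Deviations of libraries from their group means, which hold the daily rhythm that the genotypes share, were correlated between the genotypes at each time point. The correlation of deviations was over 0.1 in 12 of 12 pairs for total RNA exons (0.144 to 0.562), total RNA introns and nuclear introns, and in 11 of 12 for nuclear exons, so a fit with each time point as a block was set beside the smooth curve. Residuals around the curve correlated over 0.1 in 9, 7, 7 and 9 of 12 pairs in total exons, nuclear exons, total introns and nuclear introns (lowest -0.205). The models were tested on simulated data with 100 changed genes of each size and noise drawn independently for each gene and library. Real residuals correlated as given above, so the shares recovered need not hold for the real data. For the genotype effect in total RNA exons (11352 genes) 79% of changes of 0.5 and 94% of changes of 1 on the log2 scale were recovered, and for nuclear introns (12055 genes) 69% and 94%. Library measures were compared by 2-sided permutation tests with 1e+05 draws. Alternatives were no scaling, quantile normalization, a pseudocount 10 times smaller or larger, no filter or 1 that is 4 times stricter, a 12 h harmonic, the time block, robust variance, no pairing by liver, and leaving out each time point. Counts were also recomputed for 100 groupings of the libraries, the real one included, and for 100 swaps of genotype within time points. For rhythms in a genotype the groupings shuffled the times of the libraries within each genotype. For the wild-type nuclear to total ratio they swapped the 2 fractions at random within livers.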

Results

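RNA was sequenced from the livers of wild-type C57BL/6 mice and of mice without a working Nono gene. Nono encodes an RNA- and DNA-binding protein of the nucleus that belongs to the DBHS family with Sfpq and Pspc1 and is found in paraspeckles. The mice were 14 weeks old, lived in 12 h of light and 12 h of darkness and ate only in the dark, and livers were taken every 2 h at 12 zeitgeber times (ZT, hours after lights on). Each liver sample was a pool of 2 mice and gave a library of total RNA and a library of nuclear RNA, so that 4 groups of 12 libraries were formed, 48 in all. The values are FPKM over exons and, separately, FPKM over introns of each gene. Exon signal of total RNA stands mostly for mature messenger RNA, and intron signal of nuclear RNA for unspliced transcripts. The depth of the libraries, worked out from the steps between low FPKM values, ran from 9.91 to 28.94 M reads (M for mega).

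Introns took 22.1% ± 1.72 (SD, n = 12) of the reads of wild-type total RNA and 18.5% ± 2.41 of those of Nono-/- total RNA, a difference larger than the spread between time points (2-sided permutation test, p = 0.00063, adjusted p = 0.00252 over 8 library measures). In nuclear RNA introns took 73.2% ± 2.14 and 74.6% ± 1.16 (n = 12 each, permutation p = 0.0456, adjusted p = 0.0913). The 10 genes with the most exon reads took 15.6% ± 0.965 of the exon reads of wild-type nuclei and 19.2% ± 1.81 of those of Nono-/- nuclei (n = 12 each, permutation p = 1e-05, the smallest that these permutations can give, adjusted p = 8e-05). The exon shares and the depths did not differ past the threshold (lowest adjusted p = 0.0865). That value was for the depth of nuclear libraries, 17.8 ± 2.10 M reads in wild type and 21.7 ± 5.31 M in Nono-/- (n = 12 each).

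**Figure D1:**
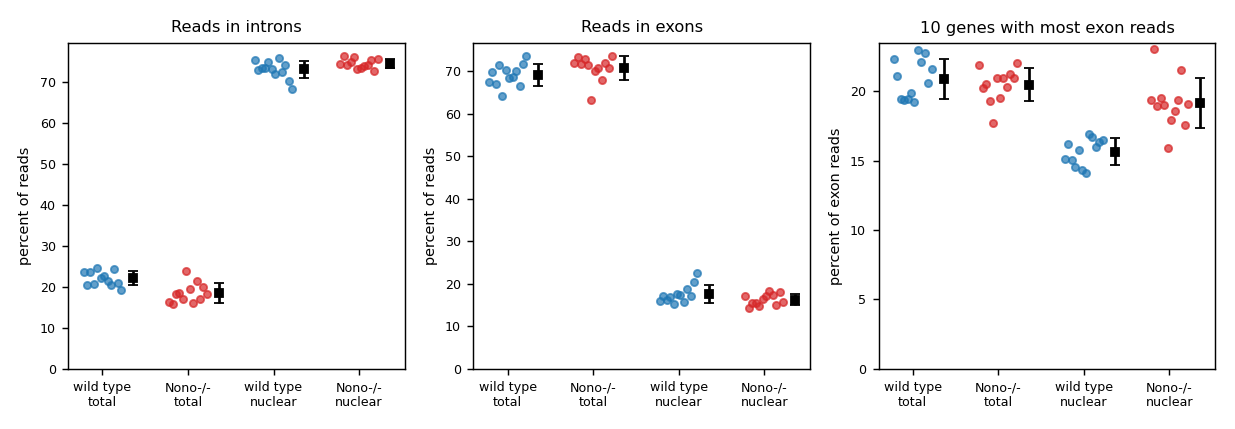
Share of reads in introns, share of reads in exons and share of exon reads taken by the 10 genes with the most reads, in percent, for each library (points, ordered by time of day within a group) with the mean and SD of the 12 libraries of a group (squares and bars). Intron reads made up 22.1% of wild-type and 18.5% of Nono-/- total RNA.

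Nono itself was read first, in every library. Its exon signal was 9.95 ± 0.594 FPKM (SD, n = 12) in wild-type total RNA, with libraries between 8.74 and 10.7 FPKM, and in Nono-/- total RNA it lay between 0 and 0.0910 FPKM, with 8 of the 12 libraries at 0. In nuclear RNA it was 2.55 ± 0.194 FPKM in wild type and between 0 and 0.0320 FPKM in Nono-/-, again with 8 of 12 libraries at 0. Every library therefore matched the genotype on its label. Nono introns kept part of their signal, with 1.42 ± 0.124 FPKM in wild-type and 0.437 ± 0.0875 FPKM in Nono-/- nuclei (n = 12 each). Nono lies on chromosome X from 101429651 to 101448593 on the plus strand of mm10. Itgb1bp2, which encodes the muscle protein melusin, starts 516 bp past its end, from 101449109 to 101453541 on the same strand. Its intron signal was 1.10 ± 0.134 FPKM in wild-type nuclei and 0 in all 12 libraries of Nono-/- nuclei, at least 299-fold lower against the limit that 3 reads over the group set. Its introns in total RNA were at least 43.8-fold lower, its exons in nuclear RNA at least 147-fold lower and its exons in total RNA at least 21.99-fold lower, again with 0 in every Nono-/- library. The next gene downstream, Taf1, starts 84142 bp past the end of Nono and had 4.41 ± 0.543 FPKM of exon signal in wild-type and 4.30 ± 0.394 FPKM in Nono-/- total RNA (limma adjusted p = 0.758). In nuclear RNA exons Taf1 had 3.80 ± 0.353 FPKM in wild type and 4.13 ± 0.465 FPKM in Nono-/-. After scaling it was higher in Nono-/- by 0.32 ± 0.08 (log2 ± SE, limma adjusted p = 0.00673). Part of that difference comes from the scaling, because the values as deposited shift the median gene by -0.20 (log2) in nuclear exons.

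**Figure D2:**
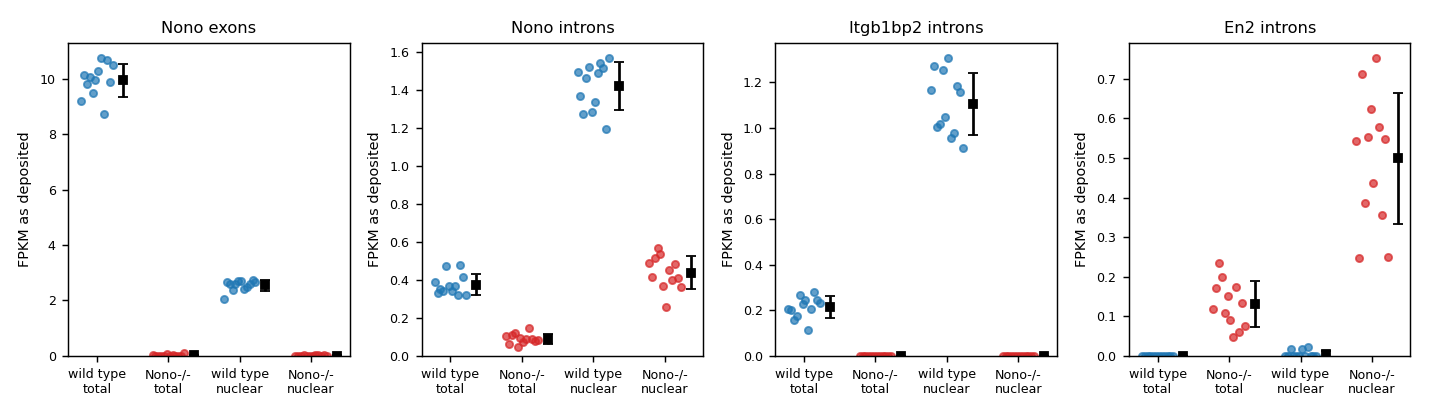
FPKM of Nono exons, Nono introns, Itgb1bp2 introns and En2 introns in each library (points, ordered by time of day within a group), with the mean and SD of the 12 libraries of a group (squares and bars). Itgb1bp2 introns are at 0 in all Nono-/- libraries and En2 introns are near 0 in wild type, 0.00467 FPKM in nuclei, and at 0.499 FPKM in Nono-/- nuclei.

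The first comparison asked which messenger RNAs differ in level between the genotypes over the whole day, from the exons of total RNA. Among the named genes that rose, Orm3, of the orosomucoid family of acute-phase glycoproteins, rose 2.76-fold (log2 change 1.46 ± 0.33 SE, limma adjusted p = 0.00954, higher at 11 of 12 time points). Hamp2, a hepcidin gene, rose from 9.09 ± 4.54 to 23.2 ± 13.5 FPKM (SD, n = 12 each). Car1, a carbonic anhydrase, rose 2.26-fold at 12 of 12 time points (limma adjusted p = 3.1e-06), and Asns, the enzyme that makes asparagine, rose 2.16-fold. Ubd, a ubiquitin-like modifier, rose 2.14-fold, the C-type lectin gene Clec2h 2.04-fold and the toll-like receptor gene Tlr13 1.96-fold. Tlr13 lies on chromosome X, as Nono does, and an effect of sequence linked to the Nono allele was not tested. Fbxo36, an F-box gene, rose 1.97-fold at all 12 time points and Cib3 rose 1.87-fold. Nono's partner gene Pspc1 rose from 2.95 ± 0.521 to 5.39 ± 0.753 FPKM, by 0.83 ± 0.08 (SE) on the log2 scale at 12 of 12 time points (limma adjusted p = 2.1e-06). Sfpq had 15.5 ± 2.82 and 15.8 ± 2.83 FPKM (log2 difference 0.01, adjusted p = 0.964).

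After Nono, the genes that fell most in total RNA exons included Mup21, a major urinary protein (149 ± 38.4 to 71.6 ± 26.0 FPKM, lower at 12 of 12 time points). Wwox, a putative tumour suppressor, fell too (1.49 ± 0.216 to 0.664 ± 0.176 FPKM, log2 change -1.10 ± 0.11 SE, limma adjusted p = 2.1e-06). Mup21 belongs to a family of near-identical genes, so its share of the reads is uncertain. The core clock gene Per1 fell 1.91-fold, at 12 of 12 time points (log2 change -0.93 ± 0.23 SE, limma adjusted p = 0.0129), and Noct, a rhythmic gene related to deadenylases, fell 1.76-fold. Cabyr fell 2.01-fold and Tmem265 fell 1.75-fold. Of the named genes, 4 are small RNA genes inside longer genes. These were Snord8 in Chd8, which rose, and Mir6942 in Zkscan3, Mir6992 in Stx5a and Mir5113 in Tnrc6b, which fell, and their reads cannot be told from those of the host transcript. In all, 510 genes were higher and 746 lower in Nono-/- among 11352 tested (limma, Benjamini-Hochberg adjusted p under 0.05).

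Of 19 measured genes on the list of lipogenesis, the synthesis of fatty acids, 5 fell in total RNA exons, 0 rose and 14 did not pass, and 9 fell when adjusted over the list alone. Fasn, the fatty acid synthase, fell 1.55-fold (log2 change -0.63 ± 0.17 SE), Me1, the malic enzyme that supplies NADPH, fell 1.49-fold, and Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, fell by 0.46 ± 0.12 on the log2 scale. The list as a whole had a median of -0.23 (camera adjusted p = 0.00020, adjusted p = 0.483 with an estimated correlation). On the insulin signalling list 4 of 16 genes fell and 5 did so adjusted over the list alone. They included Irs1, an adaptor of the insulin receptor (-0.48 ± 0.08), the receptor gene Insr (-0.33 ± 0.08) and Foxo1, a transcription factor held back by insulin (-0.46 ± 0.10). Its median was -0.10 (camera adjusted p = 0.0208, adjusted p = 0.279 with an estimated correlation). Cholesterol synthesis genes had 3 of 23 lower, also adjusted over the list alone, among them Srebf2, a transcription factor of cholesterol synthesis, at -0.49 ± 0.15 (median -0.13, camera adjusted p = 0.0355, fry adjusted p = 0.465, adjusted p = 0.948 with an estimated correlation). On the core clock list 2 of 17 fell, Per1 and Hlf, also 2 adjusted over the list alone (camera adjusted p = 0.0197, but 0.0639 with a filter 4 times stricter, and adjusted p = 0.483 with an estimated correlation).

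Of 12 markers of Kupffer cells, the macrophages of the liver, 5 rose in total RNA exons and 7 did not pass, and 8 rose adjusted over the list alone. Timd4 rose by 0.46 ± 0.12 (log2 ± SE), Cd5l by 0.44 ± 0.12 and Adgre1, which encodes the F4/80 antigen, by 0.35 ± 0.10, with a list median of 0.33 (camera adjusted p = 3.7e-05, adjusted p = 0.483 with an estimated correlation). Of 19 interferon-response genes 6 rose, and 8 rose and 1 fell adjusted over the list alone. Ifit2 rose by 0.49 ± 0.09 and Gbp2 by 0.62 ± 0.11, with a list median of 0.23 (camera adjusted p = 0.00021, adjusted p = 0.499 with an estimated correlation). Markers of liver endothelial cells had a median of -0.04, with 0 of 13 past the threshold (limma; also 0 adjusted over the list alone). In the same libraries the intron share of the reads was lower in Nono-/-, 18.5% against 22.1%.

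The counts of this comparison fell to 12 higher and 11 lower genes with the intron share of each library as a covariate, a setting chosen after the data were seen. The median change of the 1256 called genes went from 0.33 to 0.26 (log2, in the direction of the call) and their median SE from 0.08 to 0.12. The exon share as a covariate, also chosen later, gave 601 higher and 787 lower genes, 992 of the 1388 called without it too (median change 0.33 before and after). With the intron share, among genes named above, Nono, Car1, Fbxo36, Clec2h, Mup21, Wwox, Pspc1 and Irs1 kept adjusted p under 0.05. With each time point as a block 923 genes were higher and 1159 lower. Without scaling, 58.6% of the calls were higher genes, against 40.6% with it. Hamp2 lost its call without ZT12 or ZT22 (highest adjusted p = 0.0540) and Mir5113 without ZT4, ZT8 or ZT12 (0.0569), and Asns, Cib3 and Noct did without any 1 of 7, 7 and 6 time points (highest adjusted p = 0.0849, 0.0840 and 0.0718). Leaving out ZT0, ZT4, ZT12, ZT14 or ZT16 left 322, 303, 333, 305 or 306 higher genes, and leaving out ZT12, ZT14 or ZT16 left 468, 484 or 428 lower genes.

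The same question was put to unspliced transcripts, from the introns of nuclear RNA. The gene with the largest rise was En2, a homeobox gene of the midbrain and hindbrain, whose introns had 0.00467 ± 0.00853 FPKM in wild-type and 0.499 ± 0.166 FPKM in Nono-/- nuclei (n = 12 each, higher at 12 of 12 time points, limma adjusted p = 3.6e-13). En2 lies on chromosome 5 from 28165696 to 28172166, and its exons had 0.00158 FPKM (1 read over the group) in wild-type and 0.0248 ± 0.0163 FPKM (23 reads) in Nono-/- nuclei and 0.00867 (7 reads) and 0.0429 FPKM (29 reads) in total RNA. Igfbp1, an insulin-repressed gene for a binding protein of insulin-like growth factors, rose 2.89-fold (log2 change 1.53 ± 0.41 SE, limma adjusted p = 0.0145), and Cyp4a12b, a fatty acid hydroxylase of male liver, rose 2.86-fold. Il1b, the interleukin 1 beta gene, rose 2.65-fold, and its reads may include those of Il1bos on the other strand. Car1, Orm3, Clec2h and Cib3, which had risen in total RNA exons, rose 2.65-, 2.59-, 2.32- and 2.23-fold. The immediate early gene Nr4a1, which is not on the fixed list of such genes, rose 2.26-fold at 12 of 12 time points and Cth, an enzyme of cysteine synthesis, rose 2.17-fold.

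Among the genes that fell in nuclear introns, Lpin1, whose product makes diacylglycerol for fat synthesis and also acts as a coregulator of transcription, dropped from 11.6 ± 8.74 to 3.87 ± 5.62 FPKM (log2 change -1.65 ± 0.39 SE, limma adjusted p = 0.00870, lower at 12 of 12 time points). Pdgfrl, a gene related to the PDGF receptors, fell 4.99-fold at all 12 time points, from 1.20 ± 1.001 to 0.125 ± 0.0592 FPKM. Gal, the galanin gene, fell 2.83-fold, and the other genes of the group were Lenep, Nme3, the snoRNA host gene Snhg9, Ntn3 and 9130230L23Rik, which fell between 2.70- and 3.93-fold. Nme3 overlaps Mapk8ip3 on the other strand, Snhg9 overlaps Snora78 and Ntn3 overlaps Tbc1d24, so their reads could not be separated. In all, 1022 genes were higher and 1141 lower among 12055 tested (limma, adjusted p under 0.05).

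Of 20 lipogenesis genes 6 fell in nuclear introns and 14 did not pass, and 7 fell adjusted over the list alone. Me1 stood at -0.90 ± 0.20 (log2 ± SE), Fads1 at -0.62 ± 0.14 and Fads2 at -0.56 ± 0.13, both desaturases, and Lpin1 as above (median -0.28, camera adjusted p = 0.0202, adjusted p = 0.946 with an estimated correlation). Paraspeckle protein genes rose in 4 of 12 cases and in 6 adjusted over the list alone. Pspc1 rose by 0.38 ± 0.07, Rbm14 by 0.23 ± 0.07 and Sfpq by 0.30 ± 0.09 (median 0.17, camera adjusted p = 0.0227, fry adjusted p = 0.0613, adjusted p = 0.946 with an estimated correlation). Of 18 interferon-response genes 6 rose, 1 fell and 11 did not pass, with 7 higher and 1 lower adjusted over the list alone. Gbp3 rose by 0.61 ± 0.11, Ifih1 by 0.40 ± 0.08 and Usp18 by 0.45 ± 0.09, and Stat2 fell by 0.28 ± 0.07 (median 0.25, camera adjusted p = 0.0202, but 0.272 with a filter 4 times stricter, and adjusted p = 0.946 with an estimated correlation). Kupffer cell markers had 4 of 12 higher, also 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0503, adjusted p = 0.946 with an estimated correlation). With the exon share of the reads as a covariate, chosen after the data were seen, 430 genes were higher and 367 lower, and Igfbp1, Clec2h, Cth, Lenep and Ntn3 lost their calls (adjusted p from 0.0569 to 0.129). The median change of called genes went from 0.36 to 0.30 (log2) and their SE from 0.10 to 0.10, and the intron share left 965 calls. Clec2h lost its call without ZT2 (adjusted p = 0.0527), Ntn3 without ZT6 (0.0513), Cth without ZT6 or ZT18 (highest adjusted p = 0.0558) and Lenep without ZT2, ZT12 or ZT22 (0.0625). Leaving out ZT6 or ZT18 left 554 or 550 higher genes, and leaving out ZT2, ZT6 or ZT18 left 756, 582 or 574 lower genes.

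The exons of nuclear RNA were compared next. In these libraries the 10 genes with the most reads took 15.6% of exon reads in wild type and 19.2% in Nono-/-, exons took 17.6% and 16.3% of the reads (permutation p = 0.0751), and 8299 ± 605 and 7548 ± 686 genes reached 1 FPKM (SD, n = 12 each). Of 9 RNAs that stay in the nucleus 8 rose, also 8 adjusted over the list alone. Among them were Malat1 (0.61 ± 0.13, log2 ± SE), Snhg11 (0.58 ± 0.12) and Kcnq1ot1 (0.44 ± 0.11), with a list median of 0.42 (camera adjusted p = 0.00084, adjusted p = 0.258 with an estimated correlation). Of 7 measured genes of the immediate early list 5 rose, also 5 adjusted over the list alone. These were Btg2 (0.94 ± 0.10), Dusp1 (0.90 ± 0.18), Jun, Egr1 and Zfp36 (camera adjusted p = 0.00425, adjusted p = 0.258 with an estimated correlation). Of 20 lipogenesis genes 10 fell and 10 did not pass, also 10 adjusted over the list alone (median -0.51, camera adjusted p = 0.00026, adjusted p = 0.367 with an estimated correlation), with Me1 at -0.97 ± 0.15 and Fads2 at -0.99 ± 0.19. The lists of glycolysis, gluconeogenesis, carbohydrate response, fatty acid oxidation with ketogenesis, and amino acid and urea metabolism had 6 of 13, 6 of 11, 9 of 16, 11 of 21 and 6 of 17 genes lower, the same counts adjusted over the list alone (camera adjusted p from 0.00300 to 0.0381, adjusted p = 0.569 with an estimated correlation in each). Without scaling glycolysis (camera adjusted p = 0.0652), gluconeogenesis (0.109), carbohydrate response (0.0847) and amino acid and urea metabolism (0.0674) did not pass, nor did carbohydrate response with a filter 4 times stricter (0.0545). Among the lower genes were Khk, the enzyme that phosphorylates fructose (-1.16 ± 0.25), Aldoa (-0.96 ± 0.20), Sds (-1.08 ± 0.25), Acaa2 (-0.62 ± 0.11) and Asl, an enzyme of the urea cycle (-0.95 ± 0.16). On the gluconeogenesis list 1 gene rose, G6pc, by 0.58 ± 0.21.

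Splicing factor genes rose in 10 of 21 cases and fell in 1, Ptbp1, in nuclear RNA exons. Srsf6 rose by 0.38 ± 0.08 and Hnrnpu by 0.41 ± 0.11 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00152, adjusted p = 0.569 with an estimated correlation). Paraspeckle protein genes rose in 5 of 11 cases and in 6 adjusted over the list alone, with Pspc1 at 0.36 ± 0.07 and Sfpq at 0.35 ± 0.10 (camera adjusted p = 0.0171, adjusted p = 0.569 with an estimated correlation). Of 12 interferon-response genes 8 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.569 with an estimated correlation). Of 11 Kupffer cell markers 4 rose, 5 adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.569 with an estimated correlation). Markers of pancreatic acinar cells, a tissue next to the liver, were lower in Nono-/- nuclear libraries, with 4 of 8 past the threshold and 6 adjusted over the list alone (median -1.66, camera adjusted p = 0.0156, fry adjusted p = 0.0605, adjusted p = 0.671 with an estimated correlation). Ctrb1 had 1.41 ± 1.44 FPKM in wild type and 0.181 ± 0.388 FPKM in Nono-/-. Without scaling the paraspeckle (camera adjusted p = 0.124) and acinar lists (0.133) did not pass, nor did the paraspeckle (0.0868), interferon (0.201) and Kupffer lists (0.0545) with a filter 4 times stricter. By size, Orm3 rose 3.15-fold, beside the small RNA genes Snord98, Mir5124b, Mir1191 and Mir6935. Snord98 lies in Ccar1, Mir6935 in Actg1, and the entry of Mir1191 spans Clock, Tmem165, Pdcl2 and Nmu, so their reads cannot be told from those of these genes. After Nono and Itgb1bp2 the largest falls were Ctrb1 and the ribosomal RNA units Mir6236 and Rn45s (log2 change -1.77 ± 0.35 SE). Mir6236 lies in sequence shared with ribosomal RNA and its values ran over a wide range, 30.7 ± 18.8 FPKM in wild type and 20.5 ± 47.9 FPKM in Nono-/-. The library kit removes ribosomal RNA, so reads of Mir6236 and Rn45s also depend on that removal. Its success cannot be told apart from group, so these falls may not mean less ribosomal RNA in nuclei.

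In nuclear RNA exons 1665 genes were higher and 1938 lower among 10500 tested (limma, adjusted p under 0.05). The division between higher and lower genes depended on the scaling, because the values as deposited, which shift the median gene by -0.20 (log2), gave 380 higher and 3398 lower genes, or 10.1% higher against 46.2%. With the exon share as a covariate, chosen after the data were seen, 479 were higher and 447 lower, as the median change of called genes went from 0.44 to 0.32 (log2) and their SE from 0.122 to 0.123. The intron share left 1048 calls and a filter 4 times stricter 876 higher and 1008 lower. Mir5124b lost its call without ZT2, ZT12 or ZT16 (highest adjusted p = 0.0725), and Snord98 and Mir1191 did without any 1 of 6 and 9 time points (0.0851 and 0.115). Leaving out ZT6, ZT18 or ZT22 left 998, 1019 or 1108 higher genes and leaving out ZT6 or ZT18 left 1160 or 1222 lower genes.

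In the introns of total RNA 8 of 11 Kupffer cell markers rose and 9 did so adjusted over the list alone. Vsig4 rose by 0.45 ± 0.10 (log2 ± SE) and Csf1r, the macrophage colony-stimulating factor receptor, by 0.40 ± 0.09 (median 0.40, camera adjusted p = 2.7e-05, adjusted p = 0.257 with an estimated correlation). Btg2 rose 2.398-fold and Dusp1, a phosphatase that acts on MAP kinases, rose 2.31-fold. These were the 2 of 5 measured genes of the immediate early list that passed, also 2 adjusted over the list alone (camera adjusted p = 0.00860, adjusted p = 0.253 with an estimated correlation). Nr4a1, an immediate early gene that is not on the list, rose 2.57-fold. Orm3 rose 3.51-fold and Igfbp1 3.26-fold. Insulin signalling genes fell in 7 of 15 cases and rose in 1, Igfbp1, with the same counts adjusted over the list alone (median -0.13, camera adjusted p = 0.0237, adjusted p = 0.253 with an estimated correlation), among them Foxo1 at -0.64 ± 0.12. Interferon-response genes rose in 4 of 13 cases, also 4 adjusted over the list alone (camera adjusted p = 0.0144, adjusted p = 0.340 with an estimated correlation). Splicing factor genes rose in 3 of 21, 5 adjusted over the list alone (camera adjusted p = 0.00956, adjusted p = 0.568 with an estimated correlation). Acute-phase genes had 1 of 16 higher, Cxcl1, and 0 adjusted over the list alone (limma, camera adjusted p = 0.0144, fry adjusted p = 0.125, adjusted p = 0.606 with an estimated correlation). Secreted plasma proteins had 2 of 20 higher, 1 adjusted over the list alone (camera adjusted p = 0.00202, adjusted p = 0.470 with an estimated correlation), and under quantile normalization the direction of the splicing factor and secreted plasma protein lists turned. Acute phase did not pass there (camera adjusted p = 0.0714) or with a filter 4 times stricter (0.154), which also ended the calls of secreted plasma proteins (0.0689) and splicing factors (0.193), and without scaling insulin signalling (0.0959) and splicing factors (0.270) did not pass. Itgb1bp2, Lpin1, Nono, Pdgfrl and Rwdd2a fell most, Lpin1 by 1.48 ± 0.34 on the log2 scale, and Rwdd2a lost its call without ZT0, ZT16 or ZT18 (highest adjusted p = 0.0671).

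Here 670 genes were higher and 836 lower among 9422 tested (limma, adjusted p under 0.05), and the intron share of these libraries, 18.5% in Nono-/- against 22.1% in wild type, differed as well. With that share as a covariate, chosen after the data were seen, 16 were higher and 10 lower, as the median change of called genes went from 0.31 to 0.18 and their SE from 0.08 to 0.10 (log2). Of the genes named above, Orm3, Igfbp1, Lpin1, Pdgfrl and Rwdd2a lost their calls there (adjusted p from 0.137 to 0.343). The exon share as a covariate, also chosen later, gave 348 and 430, a filter 4 times stricter 312 and 429, and quantile normalization 419 higher genes. The values as deposited, with a median shift of -0.21, gave 102 higher and 3444 lower, or 2.88% higher against 44.5%. Leaving out ZT0, ZT12, ZT14 or ZT18 left 384, 395, 413 or 322 higher genes, and ZT0, ZT8, ZT12 or ZT18 left 512, 550, 534 or 448 lower genes.

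**Figure D3:**
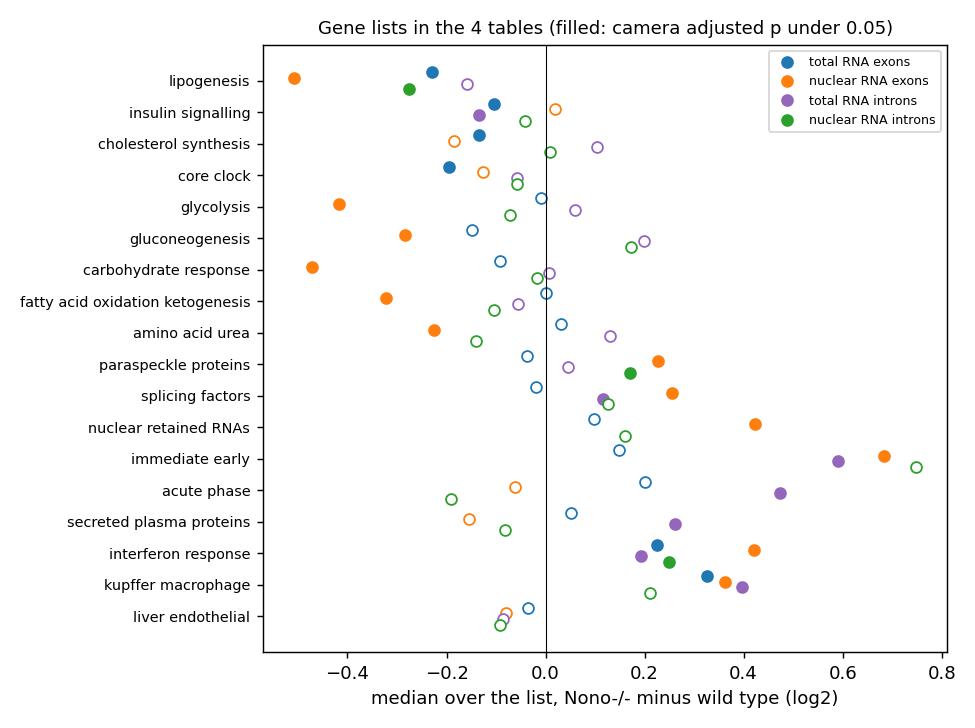
Median log2 difference between Nono-/- and wild type over the genes of each list, for exons and introns of total and nuclear RNA (colours). Filled circles have a camera adjusted p under 0.05 and none of these passes with an estimated correlation, and the lists are those past the threshold in at least 1 table, without the pancreatic acinar markers and with endothelial markers, and lipogenesis lies at -0.51 in nuclear RNA exons and -0.23 in total RNA exons.

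Of the genes higher in total RNA exons, 138 were also higher in nuclear introns, against 40.6 for independent lists, and 114 were lower in both, against 66.9. Across 10492 genes, which are not independent replicates, the genotype effects of the 2 measures correlated at 0.331. Swapping the genotypes within time points, which keeps what libraries of a liver share, gave correlations between -0.331 and 0.476 in 100 draws. The observed correlation lay inside this range, and how many draws reached it was not counted. The covariance of the effects, 0.0180, lay above the highest of the draws, 0.0161. Exons and introns of nuclear RNA correlated at 0.709 (draws 0.333 to 0.712), with 577 genes higher and 676 lower in both, against 138 and 182 for independent lists.

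**Figure D4:**
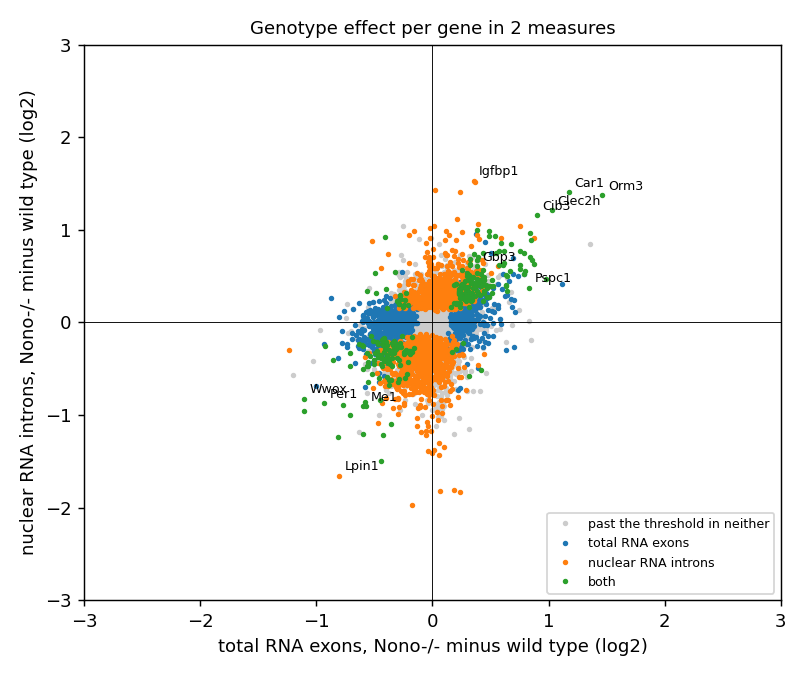
Each point is a gene, with its log2 difference between Nono-/- and wild type in total RNA exons (x) and in nuclear RNA introns (y), coloured by the measure in which the adjusted p was under 0.05. Orm3, Car1, Clec2h and Cib3 lie high in both, Lpin1, past the threshold in nuclear introns only, lies low, and Nono, at -6.48 in total RNA exons, lies outside the axes.

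A further question was whether genes keep their daily rhythm without Nono. The core clock oscillated in both genotypes. In total RNA exons Arntl, which encodes the activator BMAL1, peaked at ZT22.7 with a peak-to-trough fold of 34.3 in wild type and at ZT23.6 with 25.8 in Nono-/-. Nr1d1, which encodes the repressor REV-ERB alpha, peaked at ZT7.93 and ZT7.96, Dbp at ZT10.4 and ZT10.9, Per2 at ZT16.0 and ZT16.5, and Cry1 at ZT20.0 and ZT20.5. Of the core clock genes 15 were rhythmic in both genotypes in total RNA exons, and 12 of these peaked later in Nono-/-. In total RNA exons 3611 genes were rhythmic in wild type and 3362 in Nono-/-, 1962 of them in both (limma F test, 11352 tested). In nuclear RNA introns 2532 were rhythmic in wild type and 3855 in Nono-/-, 1630 in both, and in nuclear RNA exons 1122 and 3270, 793 in both.

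No gene passed the test of the difference in rhythm itself, with 0 genes by limma in total RNA exons, nuclear exons and nuclear introns, and 1210, 558 and 811 genes at an unadjusted p under 0.05. The genes nearest to the threshold in total RNA exons included Srebf1, the transcription factor gene of fatty acid synthesis, whose peak-to-trough fold was 5.67 in wild type, with a peak at ZT18.6, and 1.75 in Nono-/- (limma unadjusted p = 7.6e-05, adjusted p = 0.430). Srebf1 overlaps Rai1, Mir6922 and Mir6921, 1 of them on the other strand, so their reads cannot be told apart. Next to it stood Gemin6, Arsb, Celsr1 (11.2-fold and 4.20-fold), the fatty acid oxidation genes Hadhb, with peaks at ZT9.25 and ZT15.7, and Eci2, with peaks at ZT10.9 and ZT13.3, Gch1, Rpp21, Spry4 and Capn15, all with an adjusted p of 0.430 or 0.463. In nuclear introns they were A430035B10Rik, Atg101, Efna1, Atp6v1h, Zfp36l1, Trim17, Chrna9, Snrpd3, Zfp689 and Hal, the histidine ammonia-lyase gene, whose fold was 6.50 in wild type and 1.86 in Nono-/- (limma adjusted p = 0.613). A simulated loss of rhythm in Nono-/- with amplitude 1 (log2) was recovered for 84% of genes in total exons and 88% in nuclear introns. An amplitude of 0.5 gave 39% and 35%. In nuclear exons 73% and 16% were recovered. The amplitude is 0.5 of the log2 range from peak to trough, and shifts of peak time were not simulated. The simulated noise was independent between genes and libraries, unlike the residuals of the real libraries, so these shares need not hold for the real data. Leaving out the nuclear library of Nono-/- at ZT2, which stood farthest from the others and was left out after the data were seen together with wild-type total RNA at ZT8, gave 1753 rhythmic genes in Nono-/- nuclear exons. Leaving out ZT2, ZT10, ZT12, ZT16 or ZT22 in both genotypes gave 1717, 2021, 1707, 2026 or 2110. For wild type ZT8 or ZT22 left 683 or 720. In nuclear introns ZT22 left 1657 in wild type and ZT2 2533 in Nono-/-, and without ZT0 1 gene passed the test of the difference in nuclear exons.

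**Figure D5:**
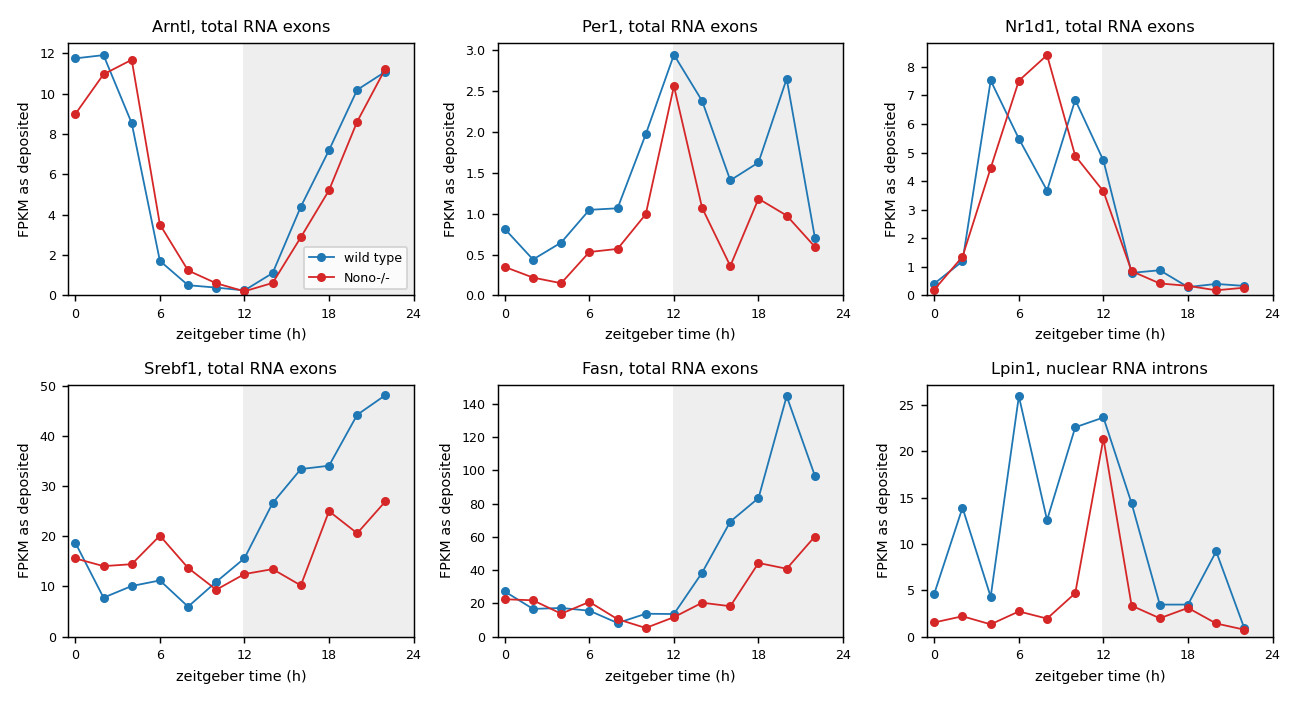
FPKM over the day of Arntl, Per1, Nr1d1, Srebf1 and Fasn in total RNA exons and of Lpin1 in nuclear RNA introns, in wild type (blue) and Nono-/- (red), 1 library per point, with the dark phase shaded. Per1 is lower in Nono-/- at 12 of 12 time points, and the fitted peak-to-trough fold of Srebf1 is 5.67 in wild type and 1.75 in Nono-/-.

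Because food was given only in the dark, dark (ZT14 to ZT0) and light (ZT2 to ZT12) libraries were compared too. The column names mark ZT14 to ZT22 as fed but not ZT0, which was counted with the dark phase that it ends. In wild-type total RNA exons 715 genes were higher and 677 lower in the dark, and in Nono-/- 341 and 266. Srebf1 was higher in the dark by 1.72 (log2) in wild type and by 0.39 in Nono-/-, a difference of -1.32 ± 0.31 (SE) that did not pass (limma unadjusted p = 0.00030, adjusted p = 0.574), and Fasn by 2.25 and 1.32. The difference between genotypes in this response passed for 0 genes by limma in total RNA exons and in nuclear introns, with 962 and 568 genes at an unadjusted p under 0.05. By lists, the dark-light difference of lipogenesis was lower in Nono-/- in total RNA exons (median -0.31, camera adjusted p = 0.0230, adjusted p = 0.938 with an estimated correlation) with 0 of 19 genes past the threshold by limma and 1 adjusted over the list alone. That of Kupffer cell markers was higher (median 0.54, camera adjusted p = 0.00408, adjusted p = 0.938 with an estimated correlation) and that of periportal hepatocyte markers lower (median -0.41, camera adjusted p = 0.0155, adjusted p = 0.938 with an estimated correlation), each with 0 genes past the threshold and 0 adjusted over the list alone. In nuclear introns, genes of the immediate early list had a lower dark-light difference in Nono-/- (median -0.57, camera adjusted p = 0.00055, adjusted p = 0.0549 with an estimated correlation). Fos stood at -1.53 ± 0.49, Btg2 at -1.30 ± 0.42 and Egr1 at -1.98 ± 0.83, with 0 of 9 past the threshold by limma and 2 lower adjusted over the list alone. Lists of lipogenesis (0.39), cholesterol synthesis (0.42), fatty acid oxidation (0.33), ribosome biogenesis (0.35) and heat shock (0.31) had higher medians and interferon response a lower one (-0.23). The camera adjusted p ran from 0.00055 to 0.00569 (lowest adjusted p = 0.753 with an estimated correlation; interferon response 0.0940 with a filter 4 times stricter), with 0 genes past the threshold by limma and 0 adjusted over the list alone in each. In neither table did a list pass with fry (0 lists each). The test has little power even with independent simulated noise. Simulated differences of 1 (log2) were recovered for 61% of genes in total RNA exons and 59% in nuclear introns, and of 0.5 for 8% and 14%. Without ZT20 1 gene passed in total RNA exons and without ZT14 1 in nuclear introns.

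Total and nuclear RNA of the same liver were then set against each other. In wild type the nuclear to total ratio differed from that of the median gene for 9782 of 11392 genes in exons, 4962 of them higher in nuclei, and for 7385 of 11371 in introns. The ratio differed between genotypes for 2070 genes in exons, 1059 higher and 1011 lower in Nono-/-, and for 2303 in introns, 1356 higher and 947 lower (limma, paired by liver). For 11 of the 24 livers the residuals of the total library correlated best with those of its own nuclear library (median 0.292 and lowest -0.299 within a liver, median -0.00629 between livers). Egr1, an immediate early transcription factor, had a higher ratio by 1.23 ± 0.28 (log2 ± SE, limma adjusted p = 0.00962, 11 of 12 time points), with 1.27 and 0.847 FPKM in wild-type and Nono-/- total RNA and 0.379 and 0.856 FPKM in nuclei. The major urinary protein gene Mup13, of the same family as Mup21, had a higher ratio by 1.31 ± 0.32 from low nuclear values (0.0236 and 0.0628 FPKM), and the small RNA genes Snord118, Snord34 and Mir133a-1 had higher ratios. These lie over Rtn3, Rpl13a and Mib1, as Mir1930 does over Ube2g2 and Mir3074-1 over Mir24-1 and 2010111I01Rik, and their reads cannot be told apart. Lower ratios were largest for Mir3074-1, Mir1930, Prss2, an acinar protease, Mir6236, with the limit on ribosomal RNA given above, and Bola2 (1.09 and 0.316 FPKM in nuclei). In introns the ratio was higher for 9330175E14Rik, Gp5, BC021767, Ifnk, which overlaps Mob3b on the other strand, and 1700012D16Rik, which overlaps St6galnac3. It was lower for Nme3 (-2.26 ± 0.37), 2210416O15Rik, 1700092M07Rik and the snoRNA host genes Snhg3 (-1.80 ± 0.43) and Snhg9. Without pairing by liver Egr1 (adjusted p = 0.0725), Prss2 (0.0609), Mir133a-1 (0.0643), Mir3074-1 (0.0542), 9330175E14Rik (0.123), Gp5 (0.135), 1700012D16Rik (0.115), 1700092M07Rik (0.164) and Snhg9 (0.102) lost their calls. Mir3074-1 did without ZT6 or ZT22 (highest adjusted p = 0.0696), Bola2 without ZT6, ZT8 or ZT22 (0.0556) and 1700012D16Rik without ZT2, ZT8 or ZT16 (0.0629). Mir133a-1, Prss2, Mir1930, Snord118, 9330175E14Rik, Gp5, 1700092M07Rik and Snhg9 did without any 1 of 11, 8, 9, 7, 8, 9, 10 and 8 time points (highest adjusted p from 0.0856 to 0.135). With a pseudocount 10 times larger Snord34 (adjusted p = 0.103), Snord118 (0.0817), Mir133a-1 (0.0777), Gp5 (0.0775) and 1700012D16Rik (0.0567) lost theirs. The values as deposited gave 4620 genes for the genotype difference in introns and 11100 for the wild-type ratio there. Without pairing 1327 and 426 genes passed in exons and introns, without the libraries that stood farthest from the others (chosen after the data were seen) 720 and 1154, and without filter 1325 in exons. Leaving out ZT0, ZT2, ZT6, ZT8, ZT12, ZT18 or ZT22 gave 3720, 1082, 798, 662, 914, 1011 or 706 genes in exons and ZT8, ZT12, ZT18 or ZT22 gave 883, 1309, 1251 or 1485 in introns.

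The ratio of exon to intron signal within a library asks whether mature and unspliced RNA changed alike. In total RNA it differed between genotypes for 678 of 8892 genes, 274 higher and 404 lower in Nono-/- (limma, adjusted p under 0.05). Among the named genes other than Nono, Igfbp1 fell by 1.35 ± 0.25 (log2 ± SE), with introns higher by 1.70 and exons at 0.35 (adjusted p = 0.598), and Slc25a25, a mitochondrial carrier, by 1.30 ± 0.14 at 12 of 12 time points. Sik1, a kinase induced by cAMP, fell by 1.24 ± 0.19, with introns higher by 0.83 and exons lower by 0.41, and G6pc, the glucose-6-phosphatase of glucose release, by 1.19 ± 0.19 at 12 of 12 time points. The ratio rose for Gfra1 (0.85 ± 0.19), Plpp1 (0.72 ± 0.11), Gm826, Hopx and Adk, the adenosine kinase (0.68 ± 0.11, at 12 of 12 time points), of which Gfra1 and Plpp1 overlap genes on the other strand. In nuclear RNA 1954 of 9823 genes differed, 876 higher and 1078 lower, with Mrpl53, Lenep, Mrpl43, Mir3473a and Foxa2, a transcription factor of liver (1.41 ± 0.29), higher and Fn3k (-1.19 ± 0.19), Zfp524, Mrps34 and Mapkapk2 (-1.15 ± 0.15) lower beside Nono. The entry of Mir3473a spans Dip2b and Mrpl53 overlaps Ccdc142, so these reads cannot be told apart. Mir3473a lost its call without ZT18 (adjusted p = 0.0557) and Mrpl43 without ZT22 (0.0524), and Hopx, Lenep and Mrps34 did without any 1 of 7, 9 and 8 time points (highest adjusted p = 0.0879, 0.0964 and 0.112). The values as deposited gave 2291 and 3183 genes and quantile normalization 448 in total RNA. Leaving out ZT0, ZT4, ZT6, ZT8, ZT12, ZT14 or ZT18 gave 321, 409, 433, 388, 383, 321 or 339 genes in total RNA, and ZT6, ZT10, ZT18 or ZT22 gave 902, 1272, 1078 or 1063 in nuclear RNA, where a filter 4 times stricter gave 1175.

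The delay between unspliced and mature RNA was taken from genes rhythmic both in nuclear introns and in total RNA exons. Its median was 2.61 h in wild type, over 1106 genes with quartiles of 0.923 and 5.04 h, and 2.98 h in Nono-/-, over 1432 genes with quartiles of 1.04 and 5.13 h. Leaving out each time point moved the medians between 2.23 and 2.70 h and between 2.49 and 3.66 h, and the difference was not tested.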

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

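The tests of an inserted construct, of transcripts running past the end of Nono, of the shares of nuclear and cytoplasmic RNA, of gene length in nuclear exons, of all non-parenchymal cells and of the interferon list with the intron share, and all counts of groupings, were chosen only after the results were seen.

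The genotype effect differed between nuclear and total RNA of the same livers, by a test of that difference, for 2070 genes in exons and 2303 in introns. Among named genes, the nuclear minus total difference of the genotype effect (log2) in exons was -1.89 for Snord8, 0.65 for Nono, whose size rests on the pseudocount, 0.52 for Noct, 0.67 for Tmem265, -2.31 for Mir6236, -1.75 for Rn45s, 2.70 for Snord118, 1.71 for Snord34, 1.49 for Mir133a-1, 1.31 for Mup13, 1.23 for Egr1, -2.67 for Mir3074-1, -2.36 for Mir1930, -2.36 for Prss2 and -1.94 for Bola2. In introns it was 0.50 for Cyp4a12b, -0.64 for Nr4a1, 0.41 for Cth, -0.57 for Itgb1bp2, -0.47 for Pdgfrl, -2.26 for Nme3, -1.78 for Snhg9, -0.33 for Dusp1, 1.39 for 9330175E14Rik, 1.13 for Gp5, 1.02 for BC021767, 0.999 for Ifnk, 0.97 for 1700012D16Rik, -2.15 for 2210416O15Rik, -1.84 for 1700092M07Rik and -1.80 for Snhg3. Itgb1bp2 introns have 0 reads in all Nono-/- libraries, so that value reflects the wild-type level and the pseudocount and tells nothing of a difference in the effect. The values of Mir6236 and Rn45s rest on reads left after the removal of ribosomal RNA, whose success cannot be told apart from group.

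En2 introns were read in Nono-/- libraries, where Itgb1bp2, which starts 516 bp past Nono, had no reads. Transcription of the whole En2 region was not borne out, since of the 3 tested genes within 500 kb 1 passed the threshold, Paxip1, and it was lower (log2 -0.15). The En2 exon to intron ratio in Nono-/- nuclei, 0.0496, lay below that of all but 0.179% of like genes, which may come from an inserted construct that carries En2 intron sequence, such as a gene trap. Wild-type Itgb1bp2 reads could be transcripts running past the end of Nono, as the exon to intron ratio in total RNA, 1.23, was lower than in all but 3.85% of like genes, though 19.6% lay lower in nuclear RNA. Both stay open, because the labels do not describe the allele, and an effect of Nono on transcription of Itgb1bp2 was not tested.

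With the intron read share of the libraries as a covariate, fewer genes passed in total and nuclear RNA, exons and introns alike. With the exon share fewer passed too, except in total RNA exons, where 1388 genes passed with it and 1256 without. In nuclear introns 2163 calls became 797 with the exon share and 965 with the intron share. In total RNA exons the intron share, which differs by genotype, also raised the median SE of called genes from 0.0846 to 0.116. Part of the fall in calls there may therefore be lost precision. Across genes, which are not independent replicates, the total RNA exon effect correlated with the wild-type nuclear to total ratio (Spearman rho -0.392). This lay within the range of 99 swaps of genotype (-0.431 to 0.332), as the value for nuclear exons did (0.115, swaps -0.139 to 0.190). How many swaps went as far was not counted. The comparison therefore does not decide on a lower share of nuclear RNA in Nono-/- total RNA for exons. Nor does it decide on less cytoplasmic RNA for nuclear exons. For total RNA introns the correlation was -0.624, just below the lowest swap (-0.623), as a lower share of nuclear RNA there would give. However, nuclear introns also lay below their swaps (-0.0805, lowest swap -0.0728). Removing each library's length trend left 446 of the 1256 calls in total RNA exons as the median effect went from 0.33 to 0.25 (SE 0.0846 to 0.0831), so gene length bias may account for part of these, but it left 3153 of the 3603 calls in nuclear exons (0.44 to 0.43), which argues against it there. An effect of Nono on the balance of nuclear and cytoplasmic RNA stays open and was not tested.

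Of the Kupffer cell list 5 of 12 genes and of the interferon list 6 of 19 were higher in Nono-/- total RNA exons. A larger share of all non-parenchymal cells is argued against, because the Kupffer median lay 0.36 (log2) above the endothelial median, with 0.293 to 0.419 when each time point was left out. The 11 called genes lie on 8 chromosomes, so a single linked strain segment that holds all of them is argued against. Gbp2, Gbp3, Ifi44 and Cd5l lie on chromosome 3. Vsig4 lies on chromosome X, as Nono does, so linkage to the Nono allele is left open for it. A segment that acts on genes elsewhere cannot be excluded this way, since such genes may lie on any chromosome. With the intron share as a covariate the Kupffer median went from 0.33 to 0.11 and its median SE from 0.121 to 0.157, with 0 genes past the threshold by limma, and it lay under 0.5 of its first value in 11 of 12 omissions of a time point (lowest 0.0456) but at 0.301 without ZT10, so the lower intron share may account for part of it. The interferon median went from 0.23 to 0.25 (0.201 to 0.366 without each time point), so it did not fall with that covariate. The median with the covariate was not tested, and 0 genes passed by limma as the median SE rose from 0.102 to 0.142. Because the share differs by genotype, its part in the interferon rise stays open. A change in Kupffer cells or in interferon signalling stays open and untested.

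Counts were set beside 100 groupings of the libraries, the real one included. For total RNA exons 3 groupings gave as many higher and 3 as many lower genes. This share is under 0.05 before any correction for the number of counts and does not exclude chance. The real 510 and 746 genes stood against 1334 at most in another grouping. The makeup of that grouping was not examined, so a structure of the samples apart from genotype was not tested. The uncorrected share was also under 0.05 for nuclear exons (1 grouping each, 1665 and 1938 against 1194), total introns (2 and 1 groupings, 670 and 836 against 727), nuclear introns (1 each, 1022 and 1141 against 31), nuclear to total ratios (1 each, 2070 against 4 and 2303 against 968) and exon to intron ratios (1 each, 678 against 598 and 1954 against 17). Swaps of genotype within time points, which keep what libraries of a time point share, gave up to 576 and 1235 genes for the nuclear to total ratios in exons and introns and up to 18 and 1131 for the exon to intron ratios in total and nuclear RNA. For rhythms, times were shuffled within each genotype instead, and the uncorrected share was under 0.05 too (1 each). Wild type first, these were 3611 against 69 and 3362 against 679 in total exons, 1122 against 2 and 3270 against 1828 in nuclear exons and 2532 against 30 and 3855 against 418 in nuclear introns. The same held for the wild-type nuclear to total ratio, with fractions swapped at random within livers (1 each, 9782 against 7612 and 7385 against 1818). For the genotype effects the swaps gave at most 58, 1638, 25 and 252 genes one way in total exons, nuclear exons, total introns and nuclear introns.

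For differences in rhythm and in the dark-light response the 0 genes seen by limma cannot be tested this way, since no grouping gives fewer. Groupings gave up to 7, 1 and 2 genes for rhythm in total exons, nuclear exons and nuclear introns and 1014 and 57 for dark-light in total exons and nuclear introns, and swaps within time points up to 96, 1755 and 404 and 155 and 1030. Chance was not excluded for the counts at an unadjusted p under 0.05. The 1210, 558 and 811 genes of rhythm were reached by 12, 24 and 18 groupings (highest 2914, 2280 and 2338) and the 962 and 568 of dark-light by 16 and 34 (highest 3791 and 3350). Among 100 swaps within time points these were reached by 5, 32 and 22 (highest 2049, 3910 and 2893) and by 9 and 21 (highest 2296 and 3541). Moving genotype labels over part of the day can turn an effect on level into a difference in rhythm or dark-light response. Large counts in other groupings therefore need not point to a structure of the samples, and these comparisons cannot decide on chance.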

How the results depend on the processing

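The tests with read shares as covariates and without the farthest libraries were chosen only after the data were seen. Of 245 planned comparisons of 29 counts and values, 224 stayed within 1.5 times or within the spread and 21 did not. Of 100 results on named genes past a threshold, 55 kept their call throughout, and of their 2258 comparisons 257 lost the call and 0 reversed. Among these 100, calls were lost for 15 without filter, 11 and 6 with a pseudocount 10 times smaller and larger, 5 without scaling and 4 with the time block. Quantile normalization, the 12 h harmonic and robust variance each ended 3. The exon share as a covariate ended 10 of 60 and the intron share 19 of 30. Of 39 list results 24 kept theirs, and of 112 comparisons 19 lost the call and 2 reversed. The cause was not tested unless given. Values as deposited, without scaling, gave 380 higher and 3398 lower genes in nuclear exons, 102 and 3444 in total introns, 11100 for the wild-type nuclear to total ratio in introns, 4620 for its genotype difference, and 2291 and 3183 for the exon to intron ratio in total and nuclear RNA. Quantile normalization gave 419 higher genes in total introns and 448 for the exon to intron ratio in total RNA, and turned the direction of the secreted plasma protein and splicing factor lists in total introns (adjusted p signed by direction, -0.601 and -0.797). Without filter the nuclear to total ratio in exons differed for 1325 genes. A filter 4 times stricter, which tests fewer genes, left 876 higher and 1008 lower in nuclear exons, 312 and 429 in total introns, 1175 for the nuclear exon to intron ratio and 25 list tests (39 in the report). With each time point as a replicate block, 923 genes were higher and 1159 lower in total exons, and without pairing by liver 1327 and 426 genes passed for the nuclear to total ratio in exons and introns. Without the farthest libraries 1753 genes were rhythmic in Nono-/- nuclear exons, 720 and 1154 passed for the nuclear to total ratio, and effects in total exons and nuclear introns correlated at 0.395. The exon share as a covariate gave 601 higher and 787 lower in total exons, 479 and 447 in nuclear exons, 348 and 430 in total introns and 430 and 367 in nuclear introns, and the intron share 12 and 11 in total exons and 16 and 10 in total introns.

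Leaving out each time point, which also means fewer samples, gave 303 to 515 higher and 428 to 785 lower genes in total exons, 998 to 2152 and 1160 to 2417 in nuclear exons, 322 to 843 and 448 to 1003 in total introns and 550 to 1367 and 574 to 1583 in nuclear introns. Rhythmic genes ran from 2475 to 3911 and 2479 to 4026 in total exons (wild type first), 683 to 1121 and 1707 to 4341 in nuclear exons and 1657 to 2497 and 2533 to 4534 in nuclear introns. Differences in rhythm gave 0 to 1 gene in nuclear exons and 0 elsewhere, and in dark-light response 0 to 1, by limma. Ratios gave 9611 to 9800 and 7101 to 7323 genes for nuclear to total in wild type, 662 to 3720 and 883 to 2784 for its genotype difference in exons and introns, and 321 to 774 and 902 to 2689 for exon to intron in total and nuclear RNA. The peak delay ran from 2.23 to 2.70 h in wild type and 2.49 to 3.66 h in Nono-/-, and the correlation of effects from 0.261 to 0.408. Depth limits genes of low level, for which 3 reads over a group set the bound.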

Other observations

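The tests of a shift of the clock and of the exon to intron ratio of immediate early genes were chosen only after the results were seen.

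In nuclear introns Bhlhe40, a repressor that feeds back on the clock, was higher in Nono-/- by 0.74 ± 0.17 (log2 ± SE, limma adjusted p = 0.00717). It stood at -0.38 ± 0.15 in total RNA exons (limma adjusted p = 0.105) and at 0.26 ± 0.15 in nuclear exons (limma adjusted p = 0.179), neither past the threshold. Per1 differed by -0.87 ± 0.27 in nuclear introns and by -1.24 ± 0.24 in nuclear exons.

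Core clock genes rhythmic in both genotypes peaked later in Nono-/- by a mean of 0.423 h in total exons (12 of 15 genes), 0.640 h in nuclear exons (14 of 16) and 0.454 h in nuclear introns (14 of 16). A shift of the whole clock by genotype is a hypothesis that these data leave open. Exact 2-sided permutation over the 4096 swaps within time points gave p = 0.318, 0.118 and 0.148 (adjusted p = 0.318, 0.222 and 0.222), and a shift may be smaller than a sampling interval of 2 h can show.

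In introns 2 of 5 measured genes of the immediate early list, which leaves out Nr4a1, were higher in Nono-/- total RNA and 4 of 9 in nuclear RNA. There the list did not pass with camera (adjusted p = 0.189, adjusted p = 0.946 with an estimated correlation) and passed with fry (adjusted p = 0.0178). A lower exon to intron ratio of the list was tested as a hypothesis. The list median was 0.09 (log2) in nuclear RNA (6 genes, 2 higher and 0 lower past the threshold by limma, exact permutation p = 0.356, adjusted p = 0.356) and -0.31 in total RNA (5 genes, 0 higher and 2 lower, exact permutation p = 0.148, adjusted p = 0.296). Neither median could be told from chance.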
